A study of Mus musculus with 6 samples.

How the data were processed

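Gene expression was measured on 6 microarrays, 3 of wild-type and 3 of Cdk19 knockout mice. Per the labels' protocols, bone marrow of mice aged 6 to 8 weeks was flushed from the leg and hip bones and depleted of cells carrying lineage markers. Hematopoietic stem cells (HSCs) were then stained and sorted by flow cytometry. Total RNA was extracted with Trizol and labelled with biotin. The labels call the arrays biological replicates and do not say how many animals each array holds. They also do not state the sex of the mice, the markers of the gate or the part of Cdk19 that was deleted.

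The deposited table holds log2 expression values made by the authors for 65956 transcript clusters on each of the 6 arrays. A transcript cluster is the set of probes that a whole-transcript array assigns to 1 gene or transcript. The submitters' processing notes name MAS5 alone, with no version and no role. MAS5 summarises probes of 3′ arrays on a linear scale, and the deposited values do not have that form. They run from 2.04 to 19.93 with 2 decimals. The background correction, the probe summary, the normalization and the log base behind them are not given in the sources used here. The values were taken as log2, so every fold size below depends on that reading. The array medians lay between 4.40 and 4.48. Near the ceiling, 81 clusters had a value above 19.8, where a change would be compressed. No detection calls, control probes, scan dates or batches were used here, and the number of arrays limits the precision.

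The platform annotation, which is some years old, named 30604 clusters with 1 gene symbol, covering 30142 genes, and 2146 with several symbols. Another 33206 had no gene name there. Symbols of 827 clusters were updated through their gene ID with the RefSeq gene table of the mouse assembly. That table also gave gene class, chromosome, which genes neighbour each other, and gene IDs where the annotation gave none. Older symbols of list members were matched through it too. Clusters with several symbols or none were counted and not named. Some members of the gene lists, Trp53 among them, had no cluster named with that symbol alone and were not analysed here.

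The plan made before the data were examined allowed for linear values with a pseudocount. The values turned out to be on a log scale, so they were tested as deposited. The dimmest 40% of clusters by mean over all 6 arrays were left out, which set a limit of 4.09 and kept 39543 clusters. A linear model with genotype as its only term was fitted with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with an intensity trend. P-values are two-sided and Benjamini-Hochberg adjusted over all tested clusters, and a cluster was called at an adjusted p under 0.05. Standard errors (SE) are the moderated ones, and SDs are over 3 arrays. Tables were prepared with Python 3.11.15 and pandas 2.3.3 and plots with matplotlib 3.10.9.

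The design, the alternatives, 24 lists of genes by function, 11 lists of cell type markers and the rule for naming genes were all fixed before the data were examined. Each list was tested on the brightest cluster of each gene with limma's camera at a preset correlation of 0.01, which compares the list with all other named genes. The lists were tested again with camera at an estimated correlation and with fry, which asks whether the genes of a list move, on balance, one way. The p-values of lists were Benjamini-Hochberg adjusted within each of the 2 families. Counts adjusted over the list alone rank the same p-values within that list only. The naming rule took Cdk19, the Mediator kinase module, the CDK inhibitors and Mdm2. It also took the 12 largest rises and the 12 largest falls among called clusters with 1 symbol and non-overlapping groups, leaving out predicted genes. From each list it took up to 2 members with the highest and 2 with the lowest statistic, and up to 4 called members, those with the smallest p. Genes named beyond the rule are said to be chosen after their values were seen. Of 29772 clusters with a chromosome in their name and a gene of known chromosome, 94 lay on another chromosome than the gene. These included the clusters tested for 3 named genes (Mir325, Erdr1 and Mid1) and 6 list members (Rpl35, Rpl27, Cycs, Pgk1, Cflar and Fas), whose values are less certain.

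The pipeline was tested on simulated data with the spread of the 39573 clusters kept there and 200 changed clusters. It recovered 63% of changes of 1 on the log2 scale and 31% of changes of 0.5, with 1 false call among 95. The real comparison called far more clusters, 1172 higher and 1914 lower, and the Benjamini-Hochberg cut depends on how many change. These shares therefore do not measure power in the real comparison. Of 20 unshifted lists, camera called 0. The simulated clusters were drawn independently and the lists at random. This check therefore says nothing on false list calls where the genes of a list move together. Among the real lists, the estimated correlation ran from -0.12 (sex-linked) to 0.41 (oxidative phosphorylation).

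The alternatives were quantile normalization, arrays shifted to a common median, no filter or a stricter one (the dimmest 60%), moderation without the trend or with robust estimation, array weights, the replicate number as a block, a mean over all clusters of a gene, and each array left out in turn. Chosen after seeing the data were a common median over protein-coding clusters, protein-coding clusters tested alone, and protein-coding genes as the background of the list tests.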

Results

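The series profiled sorted bone marrow HSCs, the cells that renew the blood system, from wild-type mice and from mice lacking Cdk19. CDK19 is a kinase of the Mediator complex, which links transcription factors to RNA polymerase II, and is closely related to CDK8. Its title names the question: how CDK19 bears on HSC proliferation and on p53-driven transcription of p21, the cell cycle inhibitor encoded by Cdkn1a. Each genotype had 3 arrays. Correlations between arrays of 1 genotype were 0.997 to 0.998 and those between genotypes 0.994 to 0.995, across clusters, which are not independent replicates. The first principal component held 50.4% of the variance.

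In the knockout HSCs, Cdkn1a rose about 2.04-fold. Of 17 NF-kB and inflammation genes 14 rose, Cxcl2 and Ptgs2 among them, while the chemokine genes Ccl3 and Ccl4 fell (camera adjusted p = 6.3e-12; adjusted p = 0.13 with an estimated correlation). Of 36 G2/M genes 18 fell, with log2 changes no lower than -0.55, and 18 did not pass (camera adjusted p = 2.4e-11; adjusted p = 0.24 with an estimated correlation). Of 11 lymphoid-primed progenitor markers 6 fell, with Dntt at -1.34, Il7r at -1.08 and Flt3 at -0.89 (camera adjusted p = 0.034 with an estimated correlation). Whether a changed mix of sorted cells lies behind these marker and G2/M changes was not tested. Of 39 p53 targets 7 rose and 3 fell, and the list did not pass (camera adjusted p = 0.46). Of 39543 transcript clusters tested, 1172 were higher and 1914 lower in the knockout (limma, Benjamini-Hochberg adjusted p under 0.05). The median absolute log2 change among them was 0.53, and 159 rose and 187 fell by at least 1 on the log2 scale. Groups did not overlap in 26.5% of clusters, against 10% by chance for 3 arrays against 3. Among protein-coding clusters 608 were higher and 758 lower. Classes of small noncoding RNA differed: 70 of 88 ribosomal RNA clusters, mainly 5S copies, were called lower and 0 higher (median log2 change -0.65), and 218 of 747 snRNA clusters lower and 1 higher (median -0.33). Of 774 snoRNA clusters 49 were lower and 3 higher (median 0.01), and of 410 miRNA clusters 8 were lower and 8 higher (median 0.06). Many 5S and snRNA copies are near-identical, so their clusters are not independent. The count of higher clusters was 673, 593 and 540 without wild-type array 1, 2 or 3 and 771 without knockout array 1. The count of lower clusters was 1040, 868 and 761 without wild-type array 1, 2 or 3 and 1168 without knockout array 2.

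Cdk19 itself (chromosome 10) was lower in every knockout array. Its level was 12.44 ± 0.06 (SD, n = 3) in wild type and 11.47 ± 0.05 (SD, n = 3) in knockout, a log2 change of -0.97 (SE 0.05; limma, Benjamini-Hochberg adjusted p = 3.2e-04). That is 1.95-fold lower on the scale assumed here. The labels do not say which part of the gene was removed, so probes of the cluster outside it would still report transcript. The paralogue Cdk8 was at 8.65 in wild type and 8.63 in knockout, a difference of -0.02 (SE 0.07). The other measured members of the kinase module did not pass either: Ccnc (cyclin C) differed by 0.05, Med12 by -0.09, Med12l by 0.24, Med13 by 0.09 and Med13l by 0.14. The kinase module list had 7 tested members with Cdk19 the 1 that fell, also adjusted over the list alone, where 1 rose too (camera adjusted p = 0.92; the list's median was 0.05, or 0.01 without knockout array 1, and its mean -0.08). In the Mediator core, 1 of 25 tested members rose, Med29 by 0.57, also 1 adjusted over the list alone (camera adjusted p = 0.92).

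Cdkn1a (chromosome 17), encoding p21, rose from 15.82 ± 0.04 (SD, n = 3) to 16.85 ± 0.06 (SD, n = 3). The log2 change was 1.03 (SE 0.04; limma, Benjamini-Hochberg adjusted p = 1.5e-04), with all 3 knockout arrays above all 3 wild-type arrays. Cdkn1b, encoding the related inhibitor p27, differed the other way, from 9.31 ± 0.07 to 8.71 ± 0.21, by -0.59 (SE 0.11; limma, Benjamini-Hochberg adjusted p = 0.023). Its call was lost without wild-type array 1 (adjusted p = 0.082), 2 (0.091) or 3 (0.069) and without knockout array 1 (0.052). Cdkn1c differed by 0.04, Cdkn2a by 0.07, Cdkn2c by -0.10 and Cdkn2d by 0.02, and none of these passed. Cdkn2b was too dim to test. Of the 6 CDK inhibitors tested, 1 rose and 1 fell, the same counts as adjusted over the list alone (camera adjusted p = 0.54; fry adjusted p = 0.0043).

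**Figure D1:**
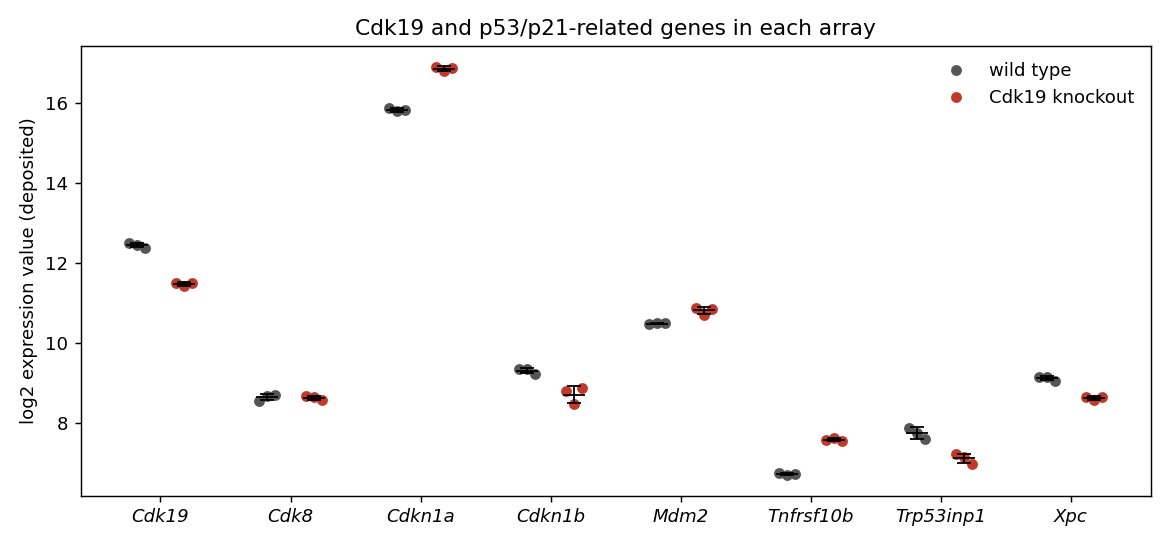
Deposited log2 expression values of Cdk19, Cdk8, the CDK inhibitors Cdkn1a and Cdkn1b, and the p53 targets Mdm2, Tnfrsf10b, Trp53inp1 and Xpc on each of the 3 wild-type (grey) and 3 knockout (red) arrays. Horizontal marks are means and bars SDs; Cdk19 lies near 12.44 in wild type and 11.47 in knockout, and Cdkn1a near 15.82 and 16.85.

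The targets of p53, the transcription factor activated by DNA damage and other stresses, split in both directions. Of 39 tested, 7 rose, 3 fell and 29 did not pass, and adjusted over the list alone 8 rose and 7 fell. Besides Cdkn1a, the rises were Plk3 by 0.94, Tnfrsf10b (a death receptor) by 0.86, Dyrk3 by 0.56, Cd80 by 0.45, Rps27l by 0.40 and Mdm2, which marks p53 for degradation, by 0.33. The falls were Trp53inp1 with a log2 change of -0.63, Sesn1 with -0.59 and the DNA repair gene Xpc with -0.49. Cd80, Rps27l and Sesn1 were chosen after their values were seen. The list's median log2 change was 0.02 and its test did not pass (camera adjusted p = 0.46; adjusted p = 0.91 with an estimated correlation; fry adjusted p = 0.079). These tests look for a shift one way, so they say little on targets that move both ways. The form of fry for changes in either direction passed the list (adjusted p = 2.6e-06). That form also passed every other list except ribosomal proteins (0.51) and oxidative phosphorylation (0.11), so it does not set the p53 targets apart. The list's median turned to -0.01 when arrays were shifted to a common median.

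The Mdm2 call was lost in 5 of the 6 runs that left out 1 array. Its adjusted p from limma was 0.024 with all arrays and 0.084, 0.090 and 0.098 without wild-type array 1, 2 or 3. It was 0.068, 0.020 and 0.067 without knockout array 1, 2 or 3 and 0.069 with arrays shifted to a common median. Trp53inp1 lost its call without wild-type array 2 (adjusted p = 0.061), where 1 target was still called lower. Sesn1 lost it without wild-type array 2 (0.074) or 3 (0.077) or knockout array 3 (0.057). Rps27l lost it in each of the 6 runs that left out 1 array and with a common median (adjusted p = 0.052). Among 14 regulators of the p53 pathway, Mdm2 was the 1 that rose, and Chek2, a checkpoint kinase, fell with a log2 change of -0.73. Mdm4, an inhibitor of p53, had a log2 change of -0.47 and lost its call without wild-type array 1 (adjusted p = 0.068), 2 (0.074) or 3 (0.051). Adjusted over the list alone, 1 regulator rose and 3 fell. The regulators' median was 0.01 and their mean -0.07, the median changed sign when arrays were shifted to a common median, and camera gave an adjusted p of 0.92.

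The largest rise was that of Thbs1, encoding the matrix protein thrombospondin, by 3.54 on the log2 scale (SE 0.08), from 6.37 to 9.91, or 11.6-fold. Nlrp3, an inflammasome sensor, rose by 2.78, Tgm2 (a transglutaminase) by 2.77, Dgat1 (triglyceride synthesis) by 2.38 and Plaur (the urokinase receptor) by 2.32. The neutrophil-attracting chemokine gene Cxcl2 rose by 2.14, and the transcription factor genes Bhlhe40 and Fosl2 by 2.08 and 1.79, while Nr4a3 rose 3.99-fold. Ptgs2, encoding the prostaglandin enzyme COX-2, rose by 1.82. A cluster named for the microRNA gene Mir325 rose by 1.98, but its name places it on chromosome 13 and the gene lies on X, so what it reports is uncertain. The cluster of the immunoglobulin segment Igh-VS107 rose by 2.13. Adjusted p-values of these 12 ran from 2.8e-05 to 0.0025 (limma, Benjamini-Hochberg).

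Among the largest falls, the chemokine genes Ccl3 and Ccl4 each fell by 1.51, Ccl3 from 15.28 to 13.78. Mc5r, a melanocortin receptor gene, fell by 2.40 and the pseudogene Pisd-ps3 changed by -1.62. Erdr1 and Mid1 fell by 1.96 and 1.90. Mid1 spans the edge of the pseudoautosomal region, in which Erdr1 lies, and both Mid1 clusters were called lower, with log2 changes of -1.90 and -1.01. An immunoglobulin kappa variable segment had the largest fall of all, with a log2 change of -3.12 (SE 0.21). Immunoglobulin segments are a family of similar copies, so which copy this cluster and that of Igh-VS107 report is uncertain. The other 5 were small noncoding RNAs: Snora73b (-1.98), Snora73a (-1.88), Scarna6 (-1.77), n-R5s115 (-1.80) and n-R5s88 (-1.61), the last of which are 5S copies. Adjusted p-values of the 12 falls ran from 5.5e-05 to 0.0036 (limma, Benjamini-Hochberg).

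**Figure D2:**
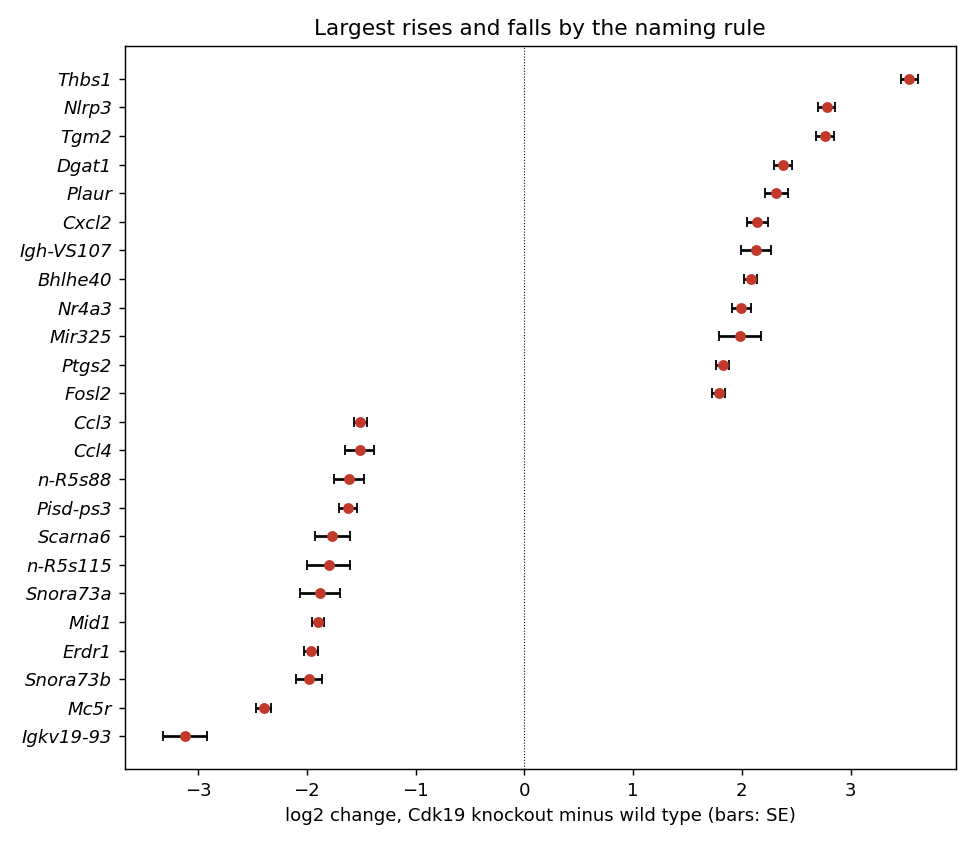
Log2 change (knockout minus wild type) of the 12 largest rises and 12 largest falls taken by the naming rule, with bars for the SE. Thbs1 stands highest at 3.54 and an immunoglobulin kappa segment lowest at -3.12.

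Of 36 tested G2/M genes, 18 fell, 18 did not pass and 0 rose, with log2 changes of the called genes between -0.55 and -0.26. Kif11 and Kif2c, spindle motor genes, had log2 changes of -0.34 and -0.46, Prc1 (the central spindle) -0.45, Ndc80 (the kinetochore) -0.53 and Mki67, chosen after its value was seen, -0.30. Adjusted over the list alone, 26 fell and 1 rose. The G2/M median was -0.31 (camera adjusted p = 2.4e-11; adjusted p = 0.24 with an estimated correlation). Fewer G2/M genes were called lower with an array left out: 10, 5 and 5 without wild-type array 1, 2 or 3, and 12, 9 and 10 without knockout array 1, 2 or 3. Of 40 G1/S genes, 1 rose and 1 fell, the same counts as adjusted over the list alone. Ccnd2, encoding cyclin D2, was the gene that fell, by 0.44. The replication licensing gene Orc1 was higher by 0.47, a call lost with arrays shifted to a common median (adjusted p = 0.052) and without wild-type array 1 (0.085), 2 (0.10) or 3 (0.088) or knockout array 1 (0.066) or 3 (0.082). The G1/S median was -0.01 and changed sign between scalings (camera adjusted p = 0.95). In DNA repair, 5 of 22 genes fell, also adjusted over the list alone, including Mre11a (-0.34) and Rad50 (-0.28) of the break-sensing complex (camera adjusted p = 0.068). Camera passed the repair list without wild-type array 1 (0.049) or knockout array 1 (0.027) or 3 (0.0499) and with no filter (0.0086). Without wild-type array 1, 2 or 3 none of these was called, a count of 0, and without knockout array 1 or 2 the count was 3.

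Genes that mark HSCs and early progenitors fell more often than they rose. Of 34 tested, 9 fell, 1 rose and 24 did not pass, and adjusted over the list alone 12 fell and 1 rose. Lyl1, a blood stem cell transcription factor, fell by 1.33. Flt3, a receptor of early multipotent and lymphoid-primed progenitors, fell by 0.89, Meis1 by 0.86, Hlf by 0.56 and the stem cell factor receptor gene Kit by 0.47. Ifitm1 rose by 0.72. Procr differed by 0.08, Slamf1 by -0.13 and Mecom by -0.13, and these did not pass. Hlf, Procr, Slamf1 and Mecom were chosen after their values were seen. For all 34 the median was -0.12, and -0.08 without knockout array 2 (camera adjusted p = 0.0046; adjusted p = 0.47 with an estimated correlation).

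Of 11 markers of lymphoid-primed progenitors, 6 fell and 0 rose, and adjusted over the list alone 7 fell and 1 rose. Dntt, which adds bases at antigen receptor joins, had a log2 change of -1.34, the interleukin-7 receptor gene Il7r -1.08 and Notch1 -0.91. Of 11 B cell markers, 6 fell and 0 rose, also adjusted over the list alone, among them the B lineage factor gene Ebf1 (-0.83) and Ighm (-0.99), and Dntt is on both lists. Their medians were -0.31 and -0.46, the second -0.20 with no filter on dim clusters and -0.64 with a stricter one, and both lists had a camera adjusted p of 2.7e-05 and an adjusted p of 0.034 with an estimated correlation. Of 13 megakaryocyte markers, 4 rose and 0 fell, and adjusted over the list alone 6 rose. The thrombin receptor gene F2r rose by 1.15, and Itga2b (CD41) and Gp9 each by 0.56 (list median 0.17; camera adjusted p = 2.0e-06; adjusted p = 0.034 with an estimated correlation). Adjusted within each family, these 3 marker lists were the only ones of all 35 that passed at an estimated correlation. By unadjusted camera p at that correlation, the cholesterol list ranked first (0.0024). Megakaryocyte (0.0052), B cell (0.0089) and lymphoid-primed (0.0093) markers followed. The cholesterol list did not pass in its larger family of 24 lists (camera adjusted p = 0.059).

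Genes linked to quiescence moved both ways: of 25, 7 rose and 4 fell, and adjusted over the list alone 9 rose and 8 fell (camera adjusted p = 0.50). Nr4a2 rose by 1.33, Klf4 by 0.96 and Foxo1 by 0.91. Txnip, an inhibitor of thioredoxin, fell by 1.35. Without wild-type array 1, 2 or 3 the count of falls was 1 each, and without knockout array 1 it was 2. The count of rises was 4 without wild-type array 3.

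NF-kB and inflammation genes showed the most frequent rise of any list. Of 17 tested, 14 rose, 2 fell and 1 did not pass, and adjusted over the list alone 15 rose and 2 fell. Besides Cxcl2 and Ptgs2, the NF-kB feedback inhibitor genes Tnfaip3 and Nfkbia, the latter chosen after its value was seen, rose by 0.81 and 0.77. Ccl3 and Ccl4, which are also targets of NF-kB, were the 2 that fell. Over the NF-kB list the median was 0.63 (camera adjusted p = 6.3e-12; adjusted p = 0.13 with an estimated correlation). Among mature cell markers, 3 of 13 granulocyte genes rose (median 0.06; camera adjusted p = 0.070; 4 rose adjusted over the list alone). With 1 array left out that median ran from 0.04 to 0.10, and camera passed the list without wild-type array 1 (adjusted p = 0.026) or knockout array 2 (0.047). The granulocyte list passed too after quantile normalization (0.048), with a common median (0.038), with no filter (0.040) or a stricter one (0.015), with the replicate block (0.044) and by fry (0.044).

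Immediate early and stress genes split by gene. Of 27, 9 rose and 2 fell, and adjusted over the list alone 12 rose and 4 fell. Gadd45b rose by 1.70 and Atf3 by 1.56, while Myc, a driver of growth, fell by 1.15. Among early genes of this response, Fos differed by -0.03, Egr1 by -0.05 and Ier2 by -0.36, and these 3, chosen after their values were seen, did not pass. Fos lay near the ceiling of the scale, where a change would be compressed. Ier2 did pass without knockout array 3 (log2 change -0.48, adjusted p = 0.018). The list's median was 0.13, and 0.06 without knockout array 3 (camera adjusted p = 0.0014; adjusted p = 0.47 with an estimated correlation). The count of rises was 5 without wild-type array 2. The count of falls was 1 without any 1 of the wild-type arrays or knockout array 2, and also after quantile normalization or a shift to a common median.

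Of 17 TGF-beta response genes, 11 rose, 0 fell and 6 did not pass, and adjusted over the list alone 14 rose and 1 fell. Besides Bhlhe40, Skil (a feedback inhibitor of SMAD signalling) rose by 1.31, Klf10 by 1.24 and the receptor gene Tgfbr1 by 0.60. Over the TGF-beta list the median was 0.49 (camera adjusted p = 6.3e-12; adjusted p = 0.17 with an estimated correlation), and 7 were called higher without wild-type array 3. Of 33 interferon response genes, 4 fell and 3 rose, and adjusted over the list alone 6 fell and 3 rose. Usp18, a brake on interferon signalling, fell by 1.06 (list median -0.15; camera adjusted p = 0.0023; adjusted p = 0.33 with an estimated correlation). Calls in the interferon list changed with single arrays. The falls numbered 2, 1 and 1 without wild-type array 1, 2 or 3 and 1 without knockout array 1 or 2. The rises numbered 0, 0 and 1 without wild-type array 1, 2 or 3, and 0 and 1 without knockout array 1 or 3.

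Of 22 genes of the unfolded protein and integrated stress responses, 12 rose, 0 fell and 10 did not pass, and adjusted over the list alone 14 rose. Vldlr rose by 0.73, and the endoplasmic reticulum chaperone genes Hspa5 and Hsp90b1 by 0.50 and 0.45. Over these 22 genes the median was 0.41 (camera adjusted p = 2.4e-11; adjusted p = 0.13 with an estimated correlation), and 7 were called higher without wild-type array 2. Cholesterol synthesis genes rose in 7 of 19 cases with 0 falls, and adjusted over the list alone 11 rose. Sqle rose by 0.81, Fdps by 0.78, Cyp51 by 0.71 and the sterol sensor gene Insig1 by 0.63 (list median 0.25; camera adjusted p = 1.3e-09; adjusted p = 0.059 with an estimated correlation). The count was 4 without wild-type array 2 or 3. Of 23 genes of glycolysis and hypoxia, 9 rose and 0 fell, and adjusted over the list alone 12 rose. The vessel growth factor gene Vegfa rose by 1.65, the glucose transporter gene Slc2a1 by 1.18 and the hexokinase gene Hk2 by 0.71 (list median 0.21; camera adjusted p = 3.0e-05; adjusted p = 0.19 with an estimated correlation).

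Of 20 niche and adhesion genes, 8 rose and 2 fell, and adjusted over the list alone 12 rose and 2 fell. Cxcr4, the receptor that holds HSCs in the marrow, rose by 1.07, P-selectin (Selp) by 0.94 and Icam1 by 0.73. The integrin gene Itga4 fell by 0.41. The list's median was 0.19 (camera adjusted p = 2.9e-04; adjusted p = 0.27 with an estimated correlation). The count of rises was 4, 5 and 5 without wild-type array 1, 2 or 3 and 5 without knockout array 1. The count of falls was 1 without wild-type array 2 or 3.

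**Figure D3:**
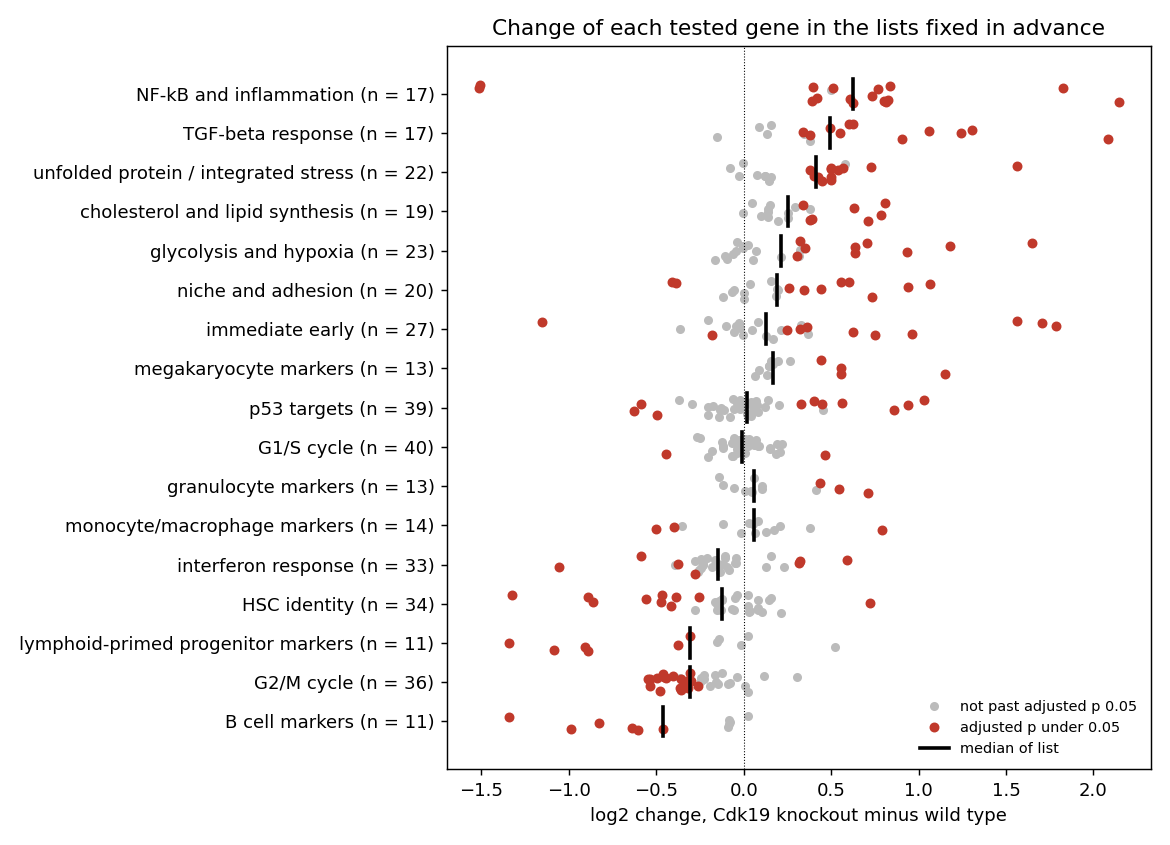
Log2 change (knockout minus wild type) of each tested gene in 17 of the lists, with genes past an adjusted p of 0.05 in red, others in grey and the list's median as a black bar. In the main fit, NF-kB genes have the highest median at 0.63 and B cell markers the lowest at -0.46. With no filter on dim clusters the B cell median was -0.20 and not the lowest. The medians of p53 targets and G1/S genes, 0.02 and -0.01, change sign between scalings.

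Genes of ribosome production and MYC targets rose in 6 of 30 cases and fell in 2, and adjusted over the list alone 12 rose and 3 fell. The polyamine enzyme gene Odc1 rose by 0.61, Ddx21 by 0.44 and Nolc1 by 0.43, while Myc itself fell. The list's median was 0.14 (camera adjusted p = 0.0014; adjusted p = 0.25 with an estimated correlation). The count of rises was 3 without wild-type array 2 or 3, and the count of falls was 1 in each run that left out an array. Of 21 ribosomal protein genes, 0 passed by limma, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.53; median 0.01, with a sign that changed between scalings). Of 39 genes of oxidative phosphorylation, 0 passed by limma, also adjusted over the list alone, and 4 were higher at an unadjusted p under 0.05, although the list's median was 0.08 (camera adjusted p = 0.0014; adjusted p = 0.69 with an estimated correlation; fry adjusted p = 0.23). Without knockout array 3 that median was 0.05 and the camera call was lost (adjusted p = 0.088). With 1 array left out, at most 1 of these genes was called higher, Cox5a at a lowest limma adjusted p of 0.040.

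A limit applies to the list tests by camera at its preset correlation. Lists passed by camera at an estimated correlation or by fry were not counted over other splits. When the 6 arrays were split in the 9 other ways, camera at its preset correlation passed up to 14 lists, against 16 for the real split. These splits are not free of the genotype difference, since each side mixes both genotypes unequally.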

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

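The Cdk19 and Cdkn1a calls held in all 17 alternatives run for each, with log2 changes of -0.997 to -0.94 and 1 to 1.17. The p53 target median ran from -0.03 to 0.03 and never passed (lowest adjusted p 0.079, by fry). With 1 array left out, between 540 and 970 clusters were higher and between 761 and 1507 lower, and 15 to 17 lists passed; fewer arrays leave less power. With an estimated correlation 3 lists passed in place of 16, and with fry 20, which gained 6 and lost the oxidative phosphorylation and antioxidant lists. Genes moving together do not account for all of the loss at an estimated correlation. For the cholesterol list that correlation was 0.0012, below the preset 0.01, yet the unadjusted camera p went from 2.6e-10 to 0.0024. For B cell markers it was -0.035, and the unadjusted camera p went from 5.6e-06 to 0.0089. Fitting the replicate number as a block gave 630 higher and 1083 lower clusters, and 1607 of these calls were shared with the fit without it. The numbers do not pair the arrays: same-numbered arrays had deviations correlating at -0.14, -0.10 and 0.02. The block uses up degrees of freedom, and the paired fit passed 17 lists. Of called clusters 62.0% were lower as deposited, 55.6% after quantile normalization and 69.2% with arrays at a common median. Chosen after seeing the data, protein-coding clusters tested alone gave 1160 higher and 1722 lower, against 608 and 758 of the same class when all clusters were tested. Of these 12803 clusters, 4466 had an unadjusted limma p under 0.05 when tested alone, against 3518 when all clusters were tested. The number of tests adjusted for is therefore not the whole cause. What changed in the moderated fit was not tested. Of 127 named genes called, 95 stayed called under every alternative run, and 0 reversed. Alternatives for other named genes kept the side of the threshold in 3044 cases, lost a call in 172 and gained it in 42; for lists these were 629, 19 and 17. The alternative pseudocount was not run, since the values are on a log scale. No signal over background was used here, so calls near the filter limit of 4.09 are the least certain.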

Other observations

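Apart from the B cell, lymphoid-primed and megakaryocyte lists, the other 8 of the 11 marker lists did not pass camera in the main fit. Of these 8, the granulocyte list passed in several alternatives, and fry passed it and the erythroid (adjusted p = 0.044), basophil (0.044), endothelial (0.013) and sex-linked (0.0031) lists. Of 14 monocyte and macrophage markers, 1 rose, Cd14 by 0.79, and 2 were lower, Irf8 and Mpeg1, with the same counts adjusted over the list alone (camera adjusted p = 0.40). Irf8 (-0.40) and Mpeg1 (-0.50) lost their limma calls without wild-type array 2 or 3, leaving 0 called lower, and 1 was called lower without wild-type array 1 or knockout array 2 or 3. Among granulocyte genes Lcn2 rose by 0.71, while the abundant Mpo differed by -0.05. Without wild-type array 2 or 3 or knockout array 1 or 3, 1 of the 3 rises was still called. Of 10 erythroid markers, 1 was lower, Car1 by -1.04, and 2 were lower adjusted over the list alone (camera adjusted p = 0.48; the median of 0.01 and the mean of -0.13 differ in sign, and the median also changed sign between scalings). Of 10 T and NK cell markers, Gzmb rose by 0.83 and Il7r fell by 1.08, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.48). Without wild-type array 1, 2 of these rose. Of 11 dendritic markers 2 rose and 2 fell, H2-Ab1 by 0.73 and Flt3 by -0.89 among them, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.92). The rises there were 1 without any 1 of the wild-type arrays or knockout array 1 or 3, and the falls 1 without any 1 of the wild-type arrays. Of 8 basophil, mast cell and eosinophil markers, 1 rose and 2 fell, the same counts as adjusted over the list alone. The eosinophil granule gene Prg2 fell by 1.07 (camera adjusted p = 0.41). Without wild-type array 3 the rise, Cpa3 by 0.41, was lost (adjusted p = 0.051), and 1 fall was called without wild-type array 2 or 3. Of 6 endothelial and stromal markers, Pecam1 was the 1 that fell, by 0.53, also adjusted over the list alone (camera adjusted p = 0.40).

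In other gene groups few members passed. Of 22 apoptosis genes 3 rose, the pro-apoptotic Bcl2l11 (BIM) by 0.58 among them, and 1 fell, Casp8 by 0.54, while adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.53; the median of -0.01 and mean of 0.03 differ in sign). The rises there numbered 1 without wild-type array 2. Of 11 Wnt and Notch target genes, 2 rose and 3 fell, the same counts as adjusted over the list alone, with Hey1 up by 1.43 and Notch1 and Myc lower (camera adjusted p = 0.93). The rises were 1 without any 1 of the wild-type arrays or knockout array 3. Of 19 antioxidant genes, Sod1 was the 1 that passed, at 0.21. It lost its call in each of the 6 runs that left out 1 array, and adjusted over the list alone 5 rose and 2 fell. The antioxidant list's median was 0.10 (camera adjusted p = 0.037; adjusted p = 0.47 with an estimated correlation; fry adjusted p = 0.091), and its camera call was lost with no filter on dim clusters (0.056) and without wild-type array 1 (adjusted p = 0.079) or knockout array 3 (0.20). Both genotypes had Xist near the filter limit, at 4.14 and 4.25, and the Y-linked Eif2s3y, chosen after its value was seen, at 8.90 and 8.76. Of 4 sex-linked genes Uty was the 1 called lower, by -0.36, and 2 were lower adjusted over the list alone (camera adjusted p = 0.15). Its call was lost without wild-type array 1 (adjusted p = 0.064), 2 (0.078) or 3 (0.062).

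The tests of bright snoRNA clusters, of level-matched 5S and snoRNA clusters apart, of granulocyte and monocyte markers, all or those low in wild type, and of the earliest stress genes below were chosen after their results were seen. The snRNA test was framed once the fall of snoRNA and 5S clusters had been noticed, and its condition on snoRNA was added after its result was seen. By its first form alone, the snRNA median would fit a lower yield of small RNA. The other tests were set before their results were seen. The bootstrap intervals in this paragraph and the next resampled clusters or genes, not arrays, so they leave out the spread between arrays. Among small noncoding RNAs in the knockout, 76 named 5S clusters had a median log2 change of -0.62 and 747 snRNA clusters one of -0.33 (95% bootstrap interval -0.36 to -0.28), while 774 snoRNA clusters had a median of 0.01. An offset from the authors' normalization that depends on intensity is argued against for the 5S copies: over 138 named snoRNA and 5S clusters, the median of the differences from protein-coding clusters matched on level was 0.66 (interval 0.60 to 0.66), and for the 5S part it was 0.67 (interval 0.66 to 0.72). For the snoRNA part it was 0.17 (interval 0.09 to 0.26), which leaves such an offset open there, as the limit set was 0.1. A loss of all small structured RNA to the same extent was tested on bright clusters, whose medians differed between classes on these arrays. Those of snoRNA with a mean above 8 had a median of -0.13 (interval -0.17 to -0.04). The snRNA clusters above that level had a median of -0.52. Both bounds of the latter were -0.52 as well, an interval of no width that does not measure uncertainty. The test relies on that bound, so it cannot decide on a loss to the same extent. A lower yield or labelling limited to some classes of small RNA may also apply. It cannot be told apart from an effect of genotype, because no extraction batch is given and near-identical copies make the clusters dependent.

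The rise of NF-kB genes (list median 0.63) may have several sources. Mature granulocytes or monocytes in the knockout sorts would raise their markers, and the test set the NF-kB median as its limit. The 27 such markers had a median change of 0.057 (95% bootstrap interval 0.0067 to 0.13). Those 17 with a wild-type mean below 8 had one of 0.053 (interval 0.0067 to 0.13). Apart, 13 granulocyte markers had a median of 0.057 and 14 monocyte markers one of 0.06, so neither set rose broadly. How far such cells would raise markers and NF-kB genes is not known, and need not be alike. The test therefore cannot decide whether such cells lie behind the NF-kB rise. A small share of them stays open, since 4 of the 27 were called higher, Lcn2 by 0.71, Cd14 by 0.79, Ctsg by 0.54 and Prtn3 by 0.43, and 2 lower, and HSCs and progenitors also express some of these markers. A stronger general handling response stays open: 8 of the earliest genes, Fos, Jun, Egr1, Ier2, Dusp1, Zfp36, Btg2 and Jund, had a median change of -0.05 (interval -0.21 to -0.0033), with Fos and Dusp1 near the ceiling of the scale, while the whole immediate early and stress list, with 9 of 27 higher, had one of 0.13 (interval -0.03 to 0.33). An effect of Cdk19 loss was not tested and stays open too.

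Some of the called genes might reflect DNA of another strain carried along with the knocked-out allele. Among the 50 tested genes on each side of Cdk19, 10 of 100 were called (10%), against 1860 of 19820 elsewhere (9.38%). The odds ratio was 1.07 (95% interval 0.50 to 2.07; Fisher's exact test, one-sided p = 0.47), too wide to settle it. The p53 target Sesn1 lies 14 tested genes from Cdk19 and is among those 10. The test covers only these neighbours of Cdk19, and a strain difference elsewhere in the genome was not tested. The breeding of the mice was not given in the sources used here.

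Of the 10 splits of the 6 arrays into 3 and 3, the real one was the 1 with as many higher clusters (1172, against at most 0 in another) and the 1 with as many lower clusters (1914, against at most 0). For lists it was again 1 of 10, with 16 passed against 14 in the highest other split. With 10 splits the share cannot go under 0.1, which is too few to reach 0.05, and the other splits keep part of the genotype difference, the rest of which adds to their spread.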
